A study of Rattus norvegicus with 12 samples.

How the data were processed

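The series describes 4 groups of adult male Wistar rats, 3 per group, with 3 procedures described as androgen deprivation that the series' design says differ in their effect on epithelial apoptosis. Per the labels' protocols, rats 90 days old were castrated by orchiectomy under ketamine (150 mg/kg) and xylazine (10 mg/kg), given 1 dose of 17β-estradiol (25 mg/kg) in corn oil, given both, or given vehicle. The ventral prostate was taken 3 days later, and 500 ng of total RNA from 30 mg of tissue was labelled as biotinylated single-stranded cDNA and hybridized to Affymetrix arrays. The design names 48 rats, and how these relate to the 12 arrays is not given in the sources used here. Immunohistochemistry is mentioned there and was not analysed here.

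Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console, with no version. The deposited values were taken as log2 expression levels, 1 per probe set and array, because their range matched that scale. The normalization, the log base and the genome build are not given in the sources used here. Every difference printed as log2 rests on that reading. Array medians lay between 5.53 and 5.76, so the deposited values had been brought close to each other, though not to identical distributions.

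The value table held 29214 probe sets and 0 columns of other samples. Of these, 15310 were paired with 1 gene symbol, 323 with several and 13581 with none. Of the 15310, 15279 matched the gene table by identifier, and 0 symbols had to be updated. Genes were tested once each: of the 527 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 14506 genes. Probe sets with several symbols or none were left out of the tests by gene.

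Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited values, with 1 mean per group over all 12 arrays, 8 residual and 5.29 prior degrees of freedom. The tests were 2-sided, and p-values were adjusted by the method of Benjamini and Hochberg over all genes, with a threshold of 0.05. All adjusted p-values of genes in the text come from limma. "Rose" and "fell" are used of genes that passed. The number of genes changed at least 2-fold counts those that passed with a log2 difference of at least 1, and is not a test against that bound. The contrasts were castrated, estradiol and combined treatment each against control, the 3 comparisons among the treated groups, and the interaction, which is the effect of estradiol in castrated animals minus that in intact animals. A moderated F test asked whether any group differed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

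Fixed lists of genes, 29 in all, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Beside it stand camera with an estimated correlation, the fry test, and counts of members adjusted over the list alone. The lists, the comparisons, the tests, the panel and the rule for naming genes were written before the data were examined. Lists share members, such as Krt19, Fkbp5, Tsc22d3 and Prlr, so their results are not independent. With an estimated correlation camera called 0 lists in every comparison, and fry called 11, 9 and 7 against control for castration, estradiol and the combined treatment, where camera called 12, 12 and 14. For combined against castrated, combined against estradiol, estradiol against castrated and the interaction fry called 0, 0, 3 and 3, where camera called 5, 15, 14 and 11.

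Genes were named by a rule. It took, for each comparison, the 6 largest rises and the 6 largest falls among genes that passed and whose arrays did not overlap between groups, without placeholder symbols, predicted genes or olfactory receptors. For the interaction it asked only that the gene passed. It added from each list described up to 4 members that passed with the largest differences, or the 1 with the smallest p if none passed, and a panel of 28 genes chosen for androgen and oestrogen action, of which 23 were measured. The other panel genes are not reported here. Msmb, Semg1, Aox3, Hpx, Pdlim3, Hectd2, Cdo1, Stx19, Fbxo33, Tmtc4, Pigr, Tgm4, Svs5 and Svs6 were named outside the rule, after their values were seen.

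Overlaps between treatments were counted by direction and set beside the product of both counts over the number of genes. They were also set beside simulated groups without effect, compared with shared simulated control arrays. Slopes of one difference on another were fitted through 0, with bootstrap intervals over genes.

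The procedure was tested on simulated data with known changes in 50 genes of each size. With equal spread on all arrays the comparison of castrated with control recovered 18%, 66%, 96% and 100% of genes changed 1.5-, 2-, 4- and 8-fold and called 0.0490% of unchanged genes. With the spread of each array taken from the data it recovered 16%, 70%, 100% and 100% and called 0%. Camera called 0% of 28 unchanged lists and called the list that had been lowered. The simulated genes varied independently of each other, so this does not test camera's calls where genes of a list are correlated. The number of arrays limits precision: changes of 1.5-fold were mostly missed at 3 arrays per group.

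The alternatives chosen before the data were examined were centring each array on its median, quantile normalization, leaving out the 33.3% of genes with the lowest mean, testing all probe sets, averaging a gene's probe sets, an intensity trend with a robust prior, fitting only the compared groups, the replicate number as a block, leaving out each array in turn, and stricter thresholds for the overlaps. Fits without estradiol arrays 1 and 2 and fits with array quality weights were chosen after seeing the data. The weights of estradiol arrays 1, 2 and 3 were 0.0879, 0.695 and 0.191. The weighted fits therefore rest the estradiol group mostly on array 2, and do not stand for a fit without arrays 1 and 2.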

Results

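Gene expression was measured in the ventral prostate, the lobe of the rat prostate that depends most visibly on testicular androgen, 3 days after treatments that the series describes as androgen deprivation. The 12 arrays fell into 4 groups of 3: intact rats given vehicle (control), rats castrated by removal of the testes, intact rats given 1 dose of 17β-estradiol at 25 mg/kg, and castrated rats given the same dose (combined treatment). Values covered 14506 genes on a scale taken as log2, so that a difference of 1 is a 2-fold change. The number of arrays, 3 per group, limited the precision. The median standard error of a difference between groups was 0.19. The labels do not tie arrays to named animals, so p-values measure the spread between these samples, which may in part be technical.

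The arrays of the control group lay apart from every treated array on the second principal component, where the treated arrays had scores of -17.8 to 4.38 and the controls reached 34.5. Estradiol arrays 1 and 2 stood apart from all other arrays. Their values had an SD of 1.93 and 2.01 over all probe sets, against 2.24 to 2.30 on the other 10 arrays. The tenth of tested genes with the lowest mean levels averaged 3.43 and 3.36 on these arrays against 2.69 to 2.84, and the tenth with the highest levels 9.23 and 9.82 against 10.0 to 10.1. Because all groups share 1 estimate of the spread, these arrays widened the errors of every comparison.

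**Figure D1:**
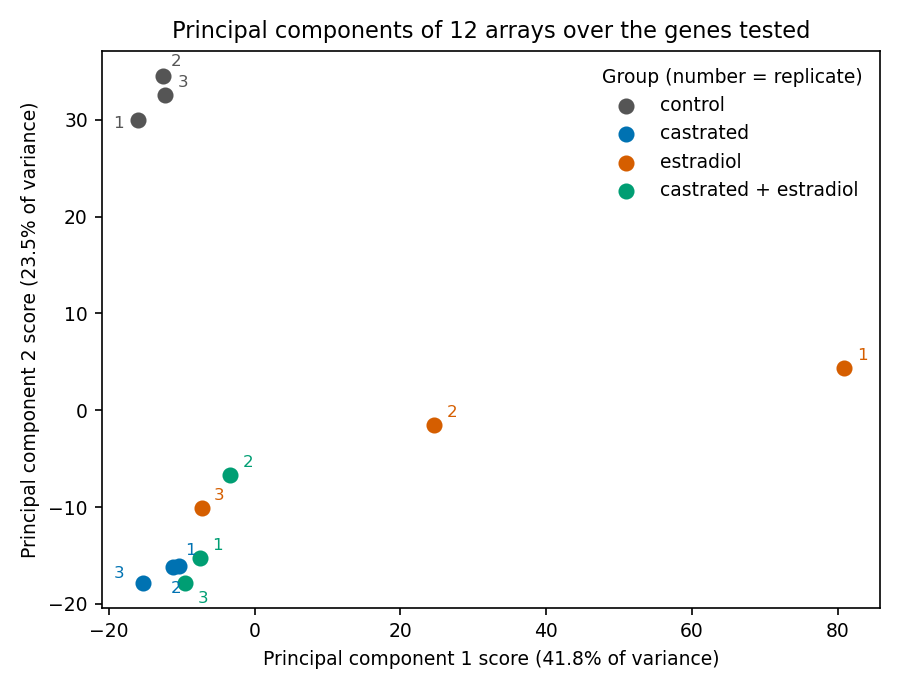
Principal component scores of the 12 arrays over the genes tested (component 1, 41.8% of variance, horizontal; component 2, 23.5%, vertical; 1 point per array, coloured by group, numbered by replicate). The 3 control arrays have the highest second scores, up to 34.5, and estradiol arrays 1 and 2 have first scores of 80.9 and 24.6 against -16.0 to -3.32 on the other arrays.

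Castrated animals were compared with controls to find what loss of the testes changed in the gland. Probasin (Pbsn), an androgen-driven secretory protein of the rat prostate, had the largest fall: it decreased by 6.57 on the log2 scale, from 11.20 ± 0.61 in controls to 4.63 ± 0.31 in castrated animals (mean ± SD, n = 3). Mep1b, which encodes a subunit of the metalloprotease meprin, had the largest rise, 23.1-fold, from 5.61 ± 0.15 to 10.14 ± 0.38. In all, 803 genes changed (5.54% of those tested), of which 460 rose and 343 fell, and 382 changed at least 2-fold (204 rose, 178 fell). Besides Mep1b, the largest rises were in Gnat2 (3.72 ± 0.51, log2 difference ± SE), Atp6v1c2, a subunit of the vacuolar proton pump (3.28 ± 0.23), Gpnmb, a glycoprotein of macrophages and other lysosome-rich cells (3.26 ± 0.35), Mmp12, the macrophage elastase (3.23 ± 0.45), and the cytochrome P450 Cyp3a9 (3.20 ± 0.48). Besides Pbsn, the largest falls were in the fatty acid hydroxylase Cyp4a8 (-4.62 ± 0.78), the whey acidic protein family member Wfdc3 (-4.59 ± 0.37), the carboxypeptidase Cpa6 (-3.82 ± 0.27), Oas1k (-3.49 ± 0.29) and Neto2 (-3.25 ± 0.28). Their adjusted p-values lay between 1.25e-06 for Mep1b and 0.00327 for Cyp4a8. The labels do not say whether animals that were only castrated received vehicle, so the injection may differ between these groups as well. Ketamine and xylazine are listed for the castrated and combined-treated groups only. Effects of surgery and anaesthesia cannot be told apart from those of losing the testes.

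The number of genes changed by castration rested on which arrays entered the fit. It was 1872 when only the 6 compared arrays were fitted and 2408 without estradiol arrays 1 and 2, which kept all 803 genes. With array quality weights it was 3788. It was 464, 361 and 399 without control 1, 2 or 3, 470 and 448 without castrated 1 or 3, and 1783 without estradiol 1.

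Most genes of protein folding in the endoplasmic reticulum, the compartment where secreted proteins mature, fell after castration. Of 35 measured, 22 fell and none rose (26 fell adjusted over the list alone), with a median of -0.75. Sdf2l1, a chaperone component, fell by 2.11 on the log2 scale, Ssr4, a subunit of the translocon complex, 2.82-fold, and Manf and Herpud1, both induced by misfolded protein, each by 1.43 on the log2 scale. The chaperone Hspa5 fell by 0.74 (adjusted p = 0.0292), a call that ended when array medians were centred and held in 13 of 21 alternatives. The list as a set was lower than other genes by limma's camera test (adjusted p = 1.61e-23), with adjusted p = 0.0567 with an estimated correlation.

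Some transcripts of lipid and polyamine synthesis fell as well. Of 24 genes of cholesterol and fatty acid synthesis, 10 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 2.23e-12, adjusted p = 0.202 with an estimated correlation). The fatty acid elongase Elovl6 fell by 2.55, the desaturase Scd by 2.11, the sterol reductase Tm7sf2 by 1.77 and the isoprenoid enzyme Idi1 by 1.72. Of 15 genes of polyamine metabolism, a pathway in which the ventral prostate is rich, 6 fell (7 adjusted over the list alone), among them spermidine synthase Srm (-1.79), Amd1 (-1.24), spermine synthase Sms (-0.99) and Mtap (-0.93). Ornithine decarboxylase, Odc1, the first enzyme of that pathway, fell by 0.81. The polyamine list had a median of -0.40 (camera adjusted p = 2.29e-06, adjusted p = 0.0818 with an estimated correlation).

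Of 20 measured secretory products of the ventral prostate, 2 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0111, adjusted p = 0.137 with an estimated correlation). Pbsn and Andpro (-1.88, adjusted p = 0.0396) fell, while Azgp1, a zinc-binding glycoprotein, rose by 2.43. The call of Andpro held in 12 of 21 alternatives. Scgb2a1, whose level lay near the top of the arrays' range (12.86 ± 0.02 in controls), differed by -0.22 (adjusted p = 0.517). The call of the list ended under quantile normalization. Androgen targets went both ways: of 24, 5 fell and 3 rose (6 and 4 adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.998. Fkbp5, a co-chaperone of steroid receptors (-1.85), Acsl3, an acyl-CoA synthetase (-1.28), and Tsc22d3 (-1.21) fell, while Ndrg1 rose by 1.60. The glucocorticoid and metallothionein list had 2 falls among 21, the same Fkbp5 and Tsc22d3 (2 adjusted over the list alone, camera adjusted p = 0.101).

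Markers of macrophages and dendritic cells had the highest median of the lists after castration. Of 26 measured, 14 rose and none fell (23 rose adjusted over the list alone), with a median of 1.23 (camera adjusted p = 1.15e-17, adjusted p = 0.19 with an estimated correlation). Cybb, the phagocyte oxidase (1.98), the adaptor Tyrobp (1.94), the pore-forming Mpeg1 (1.88) and the Fc receptor subunit Fcer1g (1.82) were among them, and Cd68 had a difference of 1.49 that did not pass (adjusted p = 0.0682). The interferon and antigen presentation list had a median of 0.50, with 2 of 36 genes rising, Ifit1 (2.65-fold) and Gbp2 (0.85), and 4 adjusted over the list alone (camera adjusted p = 4.58e-06, adjusted p = 0.462 with an estimated correlation), a list call that ended with fry. Of lymphocyte markers 1 of 25 rose, the T cell receptor chain Cd3g (0.60), with none adjusted over the list alone, and of neutrophil and mast cell markers 1 of 18 rose, Ncf1 (0.86), with 2 adjusted over the list alone. Neither list passed as a set (camera adjusted p = 0.101 and 0.761).

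Some genes of prostate regression, proteases and early response also rose. Of 29 regression genes 5 rose (5 rose and 1 fell adjusted over the list alone), among them clusterin, Clu (2.04), a marker of the regressing rat prostate, the stress gene Gadd45b (1.79), Anxa1 (1.09) and Gstm1 (0.68). Of 32 proteases and inhibitors 6 rose and 1 fell (9 and 1 adjusted over the list alone): Mmp12, cathepsin S, Ctss (1.53), and urokinase, Plau (1.23), rose, and the inhibitor Timp4 fell by 1.54. Of 26 immediate early genes 4 rose (7 rose and 1 fell adjusted over the list alone), Fosl2 (1.64), Jun (1.51), Egr1 (1.17) and Ier3 (0.69), while Fos differed by -0.03 and Junb by 0.53 (adjusted p = 0.988 and 0.0891). The camera adjusted p-values of these lists were 0.000157, 0.000928 and 0.000396, with medians of 0.35, 0.30 and 0.41. Adjusted p = 0.232, 0.25 and 0.232 with an estimated correlation, in that order.

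Some cell cycle genes rose while cyclin D1 fell. Of 31 proliferation genes 8 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 1.03e-07, adjusted p = 0.232 with an estimated correlation). Top2a (1.43), Ccna2 (1.26) and Plk1 (1.12), which act in DNA replication and mitosis, rose, and Ccnd1, which acts at entry into the cycle, fell by 1.27. Of 22 luminal epithelial markers 6 rose (8 adjusted over the list alone), with the keratins Krt19 (1.74), Krt8 (1.28) and Krt18 (0.97) and the tight junction gene Cldn4 (0.99), and a median of 0.41 (camera adjusted p = 2.37e-05, adjusted p = 0.202 with an estimated correlation). Of 40 genes of TGF-beta, Wnt, FGF and IGF signalling 2 rose and 1 fell (4 and 1 adjusted over the list alone): the receptor Met (2.16) and Smad3 (0.61) rose and Vegfa fell by 0.75, with a median of 0.18 (camera adjusted p = 0.0453, adjusted p = 0.605 with an estimated correlation). That list call ended in 11 of 20 alternatives, among them centred medians, quantile normalization, fry, the fit without dim genes and the fit without estradiol arrays 1 and 2. The call of Vegfa ended when array medians were centred (adjusted p = 0.0691) and that of Smad3 under quantile normalization (adjusted p = 0.108). That of Smad3 held in 12 of 21 alternatives.

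The other lists did not pass as sets. Of 24 steroid receptor and steroid metabolism genes, oestrogen receptor beta, Esr2 (-1.44), and Hsd17b7 (-0.71) fell and Hsd17b11 rose by 0.65 (2 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.973). Esr1 and Pgr, the oestrogen receptor alpha and progesterone receptor genes, differed by -0.24 and -0.11 (adjusted p = 0.654 and 0.944), and the 2 probe sets of Esr1 differed in sign. Of 26 oestrogen-responsive genes Krt19 rose and Fhl2 fell by 1.09, also adjusted over the list alone (camera adjusted p = 0.829). Of 40 apoptosis regulators 2 rose, Bcl2l11 (0.77) and Fadd (0.63), both pro-apoptotic, and 4 adjusted over the list alone (camera adjusted p = 0.0818), and Bcl2 differed by 0.71 (adjusted p = 0.466). Of 32 autophagy and lysosome genes 2 fell, Wipi1 (-1.02) and Atp6v1h (-0.69), also adjusted over the list alone (camera adjusted p = 0.679). Median, mean and test differed in sign for the androgen target, steroid, oestrogen-responsive, autophagy and neutrophil lists.

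Few markers of stroma and of other tissues passed after castration. Of 24 fibroblast and matrix genes 2 rose, Postn (1.16) and Col14a1 (0.83), also adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.577), and of 16 Schwann cell and nerve markers 1 fell, Nefl (-1.63), with 1 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.325). By limma no gene passed among 18 smooth muscle markers (1 at an unadjusted p under 0.05, median -0.17, Mylk 0.60), 22 endothelial markers (2, median 0.01, Ets1 0.42), 15 basal epithelial markers (2, median 0.20, Itgb4 0.53), 21 adipocyte, skeletal muscle and blood markers (3, median 0.23, Acta1 -0.91), 33 ribosomal proteins (2, median -0.04, Rpl5 0.32) and 32 genes of oxidative phosphorylation and the citrate cycle (5, median -0.11, Cox5b -0.47). None of these passed adjusted over the list alone either, and their camera adjusted p-values ran from 0.0592 to 0.922. Without estradiol arrays 1 and 2, the oxidative phosphorylation list had 2 rises and 6 falls and passed camera as lower, smooth muscle, endothelial and basal markers had 1 rise each, and adipocyte, muscle and blood markers had 1 fall. Among 12 seminal vesicle and other accessory gland genes none passed, 3 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone (median -0.07, camera adjusted p = 0.106, Svs4 -1.26 with adjusted p = 0.0562).

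**Figure D2:**
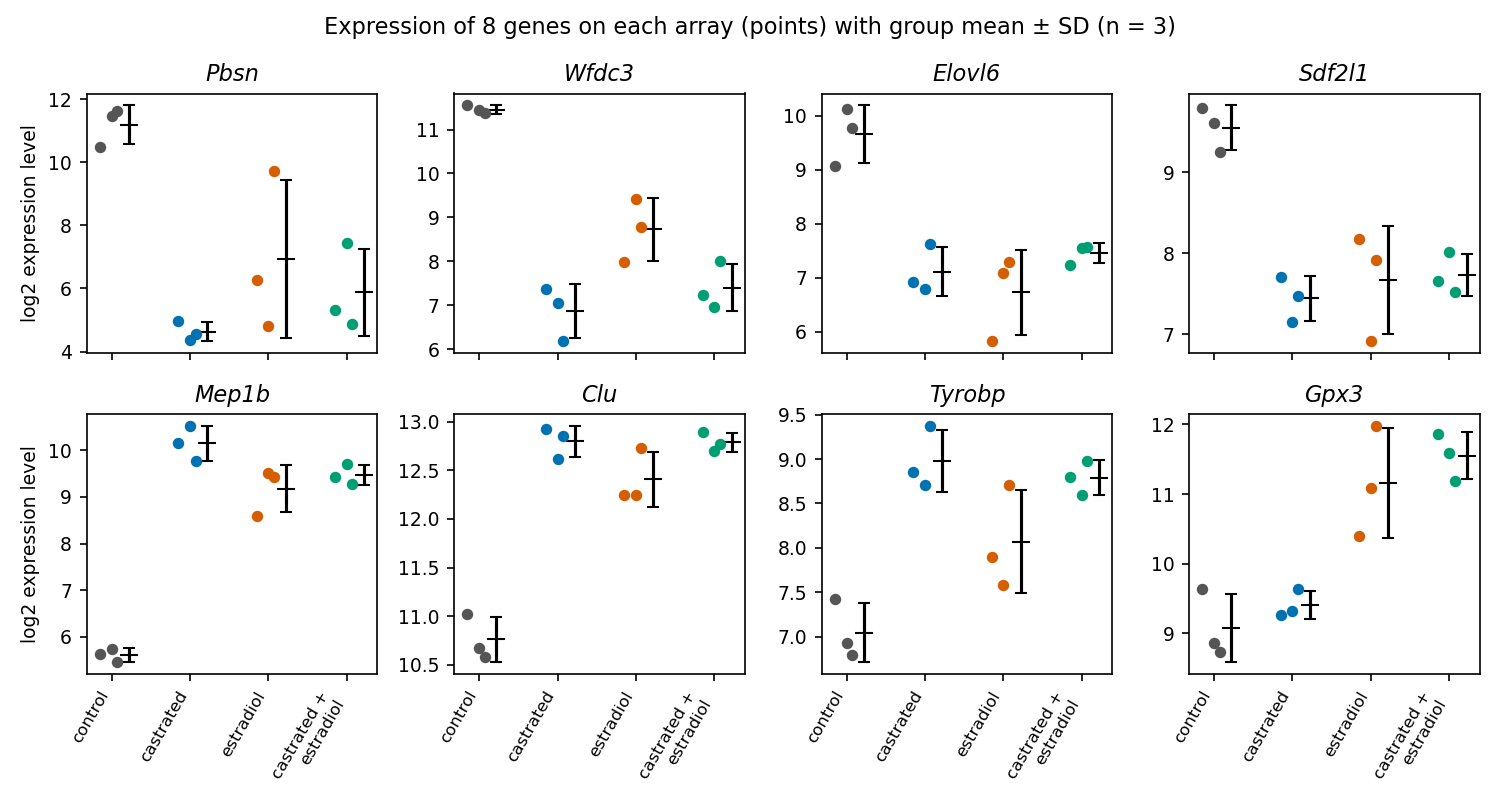
Log2 expression level of 8 genes on each of the 12 arrays (points, by group) with the group mean ± SD (bars, n = 3). Probasin (Pbsn) lies at 11.20 ± 0.61 in controls, 4.63 ± 0.31 in castrated, 6.94 ± 2.51 in estradiol-treated and 5.88 ± 1.38 in combined-treated animals, while Gpx3 is higher in both groups given estradiol (11.16 ± 0.79 and 11.55 ± 0.34) than in the other groups (9.08 ± 0.49 and 9.40 ± 0.20).

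Intact animals given estradiol were compared with controls to find what a high dose of oestrogen changed with the testes in place. The genes at the extremes were largely those named after castration. Mep1b rose 11.8-fold (3.56 ± 0.25), and Gpnmb (2.75 ± 0.35), Atp6v1c2 (2.68 ± 0.23) and Gnat2 (2.50 ± 0.51) rose with it, as did Abcc3, an exporter of organic anions (2.83 ± 0.24), and Lrrc34 (2.80 ± 0.40). Cyp4a8 (-4.67 ± 0.78), Pbsn (-4.26 ± 0.94), Cpa6 (-3.78 ± 0.27), Neto2 (-3.47 ± 0.28), Oas1k (-3.14 ± 0.29) and Elovl6 (-2.93 ± 0.36) fell. In all, 1159 genes changed (7.99%), of which 364 rose and 795 fell, and 472 changed at least 2-fold (101 rose, 371 fell). Adjusted p-values of the genes named here ran from 6.78e-06 for Mep1b to 0.0164 for Pbsn.

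This comparison rested on estradiol arrays 1 and 2. Without them 733 genes passed, 445 of the 1159 remained, and all 1159 kept their sign; the fit then holds a lone estradiol array, which is assumed to vary like the other groups. Without estradiol 3 the count was 5329. It was 432, 390 and 433 without control 1, 2 or 3, 747 without combined 1, 197 with only the 6 compared arrays, and 2307 with array quality weights. The 2-fold count was 305 and 281 without control 1 or 2 and 1237 without estradiol 3. Centring array medians, which moved the median of all genes from 0.07 to -0.05, turned the split into 202 rises and 1107 falls. It turned the other way, to 403 rises and 330 falls (178 and 157 at least 2-fold), without estradiol arrays 1 and 2. Of the 83 named genes, 36 no longer passed without estradiol arrays 1 and 2, Pbsn among them (-1.49, adjusted p = 0.353): its level was 9.71 on estradiol array 3 and at most 7.45 on the other 5 arrays of animals given estradiol.

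Cholesterol and fatty acid synthesis had the lowest median of the 29 lists under estradiol. Of 24 genes 16 fell and none rose (20 adjusted over the list alone), with a median of -1.41 (camera adjusted p = 2.72e-16, adjusted p = 0.221 with an estimated correlation). Besides Elovl6, Scd fell by 2.47, Idi1 by 2.06 and the sterol-pathway thiolase Acat2 by 1.99. Of 35 endoplasmic reticulum folding genes 20 fell and none rose (30 adjusted over the list alone), with a median of -0.86, or -0.55 without estradiol arrays 1 and 2 (camera adjusted p = 8.39e-18, adjusted p = 0.127 with an estimated correlation). Sdf2l1 (-1.88), Dnajb9 (-1.52), Herpud1 (-1.51) and Hyou1 (-1.30) fell, and without those arrays Herpud1 no longer passed (adjusted p = 0.108) and 9 of the 35 did. Of 15 polyamine genes 7 fell (8 adjusted over the list alone), with Srm (-1.53), the antizyme inhibitor Azin1 (-1.22), Amd1 (-1.18) and the arginase Arg2 (-1.12), and a median of -0.84, or -0.27 without those arrays (camera adjusted p = 0.000111, adjusted p = 0.172 with an estimated correlation). Odc1 differed by -0.27 (adjusted p = 0.319).

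Of 24 androgen targets 6 fell and 1 rose (6 and 2 adjusted over the list alone), with Fkbp5 (-1.62), Acsl3 (-1.62), Eaf2 (-1.23) and Tsc22d3 (-0.96) among the falls (camera adjusted p = 0.0946). Of 20 secretory products 2 fell, Pbsn and Andpro (-1.82), and 4 adjusted over the list alone, and as a set the list had a median of -0.04 (camera adjusted p = 0.55). Andpro did not pass without estradiol arrays 1 and 2 (-1.13, adjusted p = 0.304). Among steroid receptor and metabolism genes 3 of 24 fell, the prolactin receptor Prlr (-1.75), Esr2 (-1.73) and Hsd17b7 (1.99-fold lower), with 1 rise and 5 falls adjusted over the list alone (camera adjusted p = 0.289). Esr2 did not pass without those arrays (-1.16, adjusted p = 0.147). Of 26 oestrogen-responsive genes 2 rose, the carbonic anhydrase Car12 (1.96) and Krt19 (1.36), and 2 fell, Prlr and Fhl2 (-1.37), with 2 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.832). Esr1 differed by 0.21 and Pgr, a classical oestrogen target, by 0.38 (adjusted p = 0.437 and 0.241).

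Regression genes included 3 rises among 29 (3 adjusted over the list alone): Gpx3, the secreted glutathione peroxidase (2.08), Gadd45b (1.84) and Clu (1.65), with a median of 0.01 (camera adjusted p = 0.55), and the list passed as higher without estradiol arrays 1 and 2 (median 0.25, adjusted p = 0.00515). Among 32 proteases and inhibitors Mmp12 rose (2.36) and Timp4 (-1.23) and Mmp2 (-0.78) fell, with 4 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.631). Of 31 proliferation genes 9 rose and 1 fell (11 and 2 adjusted over the list alone), with Top2a (1.17), Plk1 (0.93) and Kif20a (0.93) rising and Ccnd1 falling by 0.99, and a median of 0.44 (camera adjusted p = 0.000193, adjusted p = 0.576 with an estimated correlation). Of 26 immediate early genes Fosl2 (1.26), Jun (0.95) and Ier3 (0.69) rose, and 5 rose adjusted over the list alone, with a median of 0.33, or 0.09 without estradiol arrays 1 and 2 (camera adjusted p = 0.0166, adjusted p = 0.576 with an estimated correlation). That list call ended without those arrays, without estradiol 1 or 3 and with array weights, and the proliferation call without estradiol 3 and with array weights. Of 40 apoptosis regulators Bid rose (0.70) and Diablo (adjusted p = 0.0458) and Cflar (-0.87) fell, also adjusted over the list alone (camera adjusted p = 0.289), and none of them passed without those arrays. Bcl2 differed by -0.74 (adjusted p = 0.229).

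Macrophage and dendritic cell markers had a median of 0.51 under estradiol, and of 1.16 without estradiol arrays 1 and 2. Of 26, 3 rose, Aif1 (1.29), Tyrobp (1.02) and the complement subunit C1qa (0.98), with 3 adjusted over the list alone and 13 without those arrays (camera adjusted p = 0.00108, adjusted p = 0.634 with an estimated correlation). Of 25 lymphocyte markers 3 rose, Cd8b (0.76), Cd3g (0.69) and Cd2 (0.62), and 4 adjusted over the list alone, with 1 without those arrays (camera adjusted p = 0.00525, adjusted p = 0.523 with an estimated correlation). Of 22 endothelial markers 4 fell (6 adjusted over the list alone), Cd34 (-1.68), Flt1 (-0.83), Eng (-0.73) and Pecam1 (-0.58), and of 18 smooth muscle markers 2 (6 adjusted over the list alone), with Cnn1 (-1.40) and Kcnmb1 (-1.22). Both lists had a median near -0.4 (camera adjusted p = 0.000476 and 0.00274, adjusted p = 0.506 and 0.576 with an estimated correlation), and none of these 6 genes passed without those arrays. Among 24 fibroblast and matrix genes limma called none, adjusted over all genes or over the list alone, 7 had an unadjusted p under 0.05, all lower, and the median was -0.39 (camera adjusted p = 0.00404, adjusted p = 0.648 with an estimated correlation; Lum -0.83). Without those arrays the macrophage, endothelial, smooth muscle and fibroblast lists still passed camera, and the lymphocyte list did not. The smooth muscle and lymphocyte calls also ended under quantile normalization, those of smooth muscle and fibroblasts without dim genes, that of fibroblasts without control 1 and that of macrophages without estradiol 3. With fry the smooth muscle, fibroblast and macrophage calls ended.

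Of 32 genes of oxidative phosphorylation and the citrate cycle 5 fell (6 adjusted over the list alone), with Cox6c (-1.09), Ogdh (-0.90), Ndufb8 (-0.85) and Ndufb5 (-0.79), and a median of -0.28 (camera adjusted p = 0.000141, adjusted p = 0.523 with an estimated correlation). Of 32 autophagy and lysosome genes Wipi1 (-1.27) and Atp6v1h (-0.63) fell, also adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.00274, adjusted p = 0.576 with an estimated correlation). Without estradiol arrays 1 and 2 none of these 6 genes passed, the medians were -0.10 and -0.04, and both list calls ended. Both also ended under quantile normalization, and that of autophagy without dim genes, without estradiol 1 and with fry. Of 22 luminal epithelial markers 4 rose and 1 fell (6 and 2 adjusted over the list alone): Krt19, Krt8 (0.81) and Krt18 (0.70) rose and the homeobox gene Hoxb13 fell by 0.86, with a median of 0.05 (camera adjusted p = 0.55). Of 36 interferon and antigen presentation genes limma called none, adjusted over all genes or over the list alone, with 3 at an unadjusted p under 0.05 (median 0.03, camera adjusted p = 0.832; Ifi44 -0.61) and 1 rise without those arrays. Leaving them out, the luminal, interferon and ribosomal protein lists passed camera as higher. Median and test differed in sign for the steroid, oestrogen-responsive and glucocorticoid lists.

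Castrated animals given estradiol were compared with controls to find what both treatments did together. Pbsn fell by 5.32 (SE 0.94), to 5.88 ± 1.38, and the other large falls were Cyp4a8 (-4.72 ± 0.78), Wfdc3 (-4.06 ± 0.37), Cpa6 (-3.97 ± 0.27), Neto2 (-3.44 ± 0.28) and Oas1k (-3.20 ± 0.29). Mep1b (3.85 ± 0.25), Gnat2 (3.62 ± 0.51), Abcc3 (3.33 ± 0.24), Mmp12 (3.28 ± 0.45), Gpnmb (3.23 ± 0.35) and Atp6v1c2 (3.08 ± 0.23) had the largest rises. In all, 627 genes changed (4.32%), 307 rising and 320 falling, and 335 changed at least 2-fold (161 rose, 174 fell). Adjusted p-values of these 12 genes ran from 3.76e-06 for Mep1b to 0.00487 for Pbsn. The count was 2871 with only the 6 compared arrays, 2105 without estradiol arrays 1 and 2 and 4134 with array quality weights. It was 387, 265 and 299 without control 1, 2 or 3, 288 and 275 without combined 1 or 3, and 1484 without estradiol 1. Centring array medians turned the split into 209 rises and 339 falls, and leaving out estradiol arrays 1 and 2 into 1104 rises and 1001 falls.

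Of 24 cholesterol and fatty acid synthesis genes 11 fell and 1 rose under the combined treatment (18 and 1 adjusted over the list alone), with Scd (-2.45), Elovl6 (-2.20), Idi1 (-2.13) and Acat2 (-2.04), and a median of -1.01 (camera adjusted p = 4.19e-19, adjusted p = 0.154 with an estimated correlation). Of 35 endoplasmic reticulum folding genes 15 fell (24 adjusted over the list alone), with Sdf2l1 (-1.82), Ssr4 (-1.36), Hyou1 (-1.30) and Manf (-1.28), and a median of -0.68 (camera adjusted p = 7.33e-24, adjusted p = 0.0543 with an estimated correlation). Of 15 polyamine genes 6 fell, also adjusted over the list alone, with Srm (-1.39), Amd1 (-1.27), Azin1 (-1.04) and Sms (-1.03), and a median of -0.33 (camera adjusted p = 8.38e-06, adjusted p = 0.111 with an estimated correlation). Of 20 secretory products Pbsn fell and Azgp1 rose (1.99), also adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0279, adjusted p = 0.158 with an estimated correlation), a list call that ended under quantile normalization, without control 1, without combined 2 and with fry. Of 24 androgen targets 5 fell and 2 rose (5 and 3 adjusted over the list alone, camera adjusted p = 0.785), with Fkbp5 (-2.04), Tsc22d3 (-1.43) and Acsl3 (-1.43) falling and Ndrg1 rising by 1.71. Esr2 fell by 2.14, Prlr by 1.21 and Hsd17b7 by 0.97, and Hsd17b11 rose by 0.72 (1 rise and 3 falls among 24 steroid genes, also adjusted over the list alone, camera adjusted p = 0.943).

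Of 29 regression genes 6 rose and 1 fell under the combined treatment, also adjusted over the list alone, with Gpx3 (2.47), Clu (2.03), Gadd45b (1.90) and Anxa1 (1.06), and a median of 0.39 (camera adjusted p = 1.19e-05, adjusted p = 0.181 with an estimated correlation). Of 26 macrophage and dendritic cell markers 8 rose (18 adjusted over the list alone), with Tyrobp (1.75), C1qb (1.62), Cybb (1.48) and Mpeg1 (1.39), and a median of 1.08 (camera adjusted p = 3.01e-13, adjusted p = 0.181 with an estimated correlation). The calls of C1qb, Cybb and Mpeg1 ended when array medians were centred, and held in 11, 10 and 11 of 21 alternatives. Of 26 immediate early genes 5 rose (9 adjusted over the list alone), with Fosl2 (1.57), Egr1 (1.34), Jun (1.24) and Ier3 (0.76), and a median of 0.37 (camera adjusted p = 4.74e-06, adjusted p = 0.158 with an estimated correlation). Of 22 luminal epithelial markers 7 rose (7 rises and 1 fall adjusted over the list alone), with Krt19 (1.82), Cldn3 (1.23), Cldn4 (1.15) and Krt8 (1.06), and a median of 0.41 (camera adjusted p = 0.000125, adjusted p = 0.181 with an estimated correlation). Of 32 proteases and inhibitors 4 rose and 1 fell (7 and 1 adjusted over the list alone), with Plau (1.36) and Adamts1 (1.17) rising and Timp4 falling by 1.54, and a median of 0.23 (camera adjusted p = 0.00206, adjusted p = 0.323 with an estimated correlation; the list call ended with fry).

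Of 31 proliferation genes Plk1 rose (1.01) and Ccnd1 fell by 0.81 under the combined treatment, and adjusted over the list alone 12 rose and 1 fell, with a median of 0.48 (camera adjusted p = 4.74e-06, adjusted p = 0.323 with an estimated correlation). Of 40 growth factor signalling genes Met rose (2.03), with 5 rises adjusted over the list alone and a median of 0.19 (camera adjusted p = 0.0177, adjusted p = 0.639 with an estimated correlation). Of 32 oxidative phosphorylation genes Cox5b fell by 0.52, also adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0197, adjusted p = 0.639 with an estimated correlation). Of 36 interferon and antigen presentation genes limma called none, adjusted over all genes or over the list alone, with 4 at an unadjusted p under 0.05 and 2 rises without estradiol arrays 1 and 2 (median 0.33, camera adjusted p = 0.00375, adjusted p = 0.699 with an estimated correlation; Psmb8 0.62). Among 15 basal epithelial markers it called none in either way, with 3 at an unadjusted p under 0.05 and 3 rises without those arrays (median 0.24, camera adjusted p = 0.0177, adjusted p = 0.323 with an estimated correlation; Itgb4 0.64). No apoptosis regulator of 40 passed in either way, with 11 at an unadjusted p under 0.05 and 7 rises and 3 falls without those arrays (median 0.11, camera adjusted p = 0.14), and Bcl2l11 and Bcl2 differed by 0.65 and 1.04 (adjusted p = 0.0546 and 0.222). Medians of the smooth muscle, endothelial, fibroblast and lymphocyte lists lay between -0.01 and 0.12 and none passed as a set. With fry the calls of the proliferation, growth factor, oxidative phosphorylation, interferon and basal lists ended. Quantile normalization ended those of oxidative phosphorylation and basal markers. Leaving out 1 array ended those of growth factor signalling (control 2, combined 3), oxidative phosphorylation (control 3, combined 2), interferon (combined 3) and basal markers (control 2). Median, mean and test differed in sign for the androgen target, steroid, autophagy, smooth muscle, endothelial, neutrophil, adipocyte, accessory gland and glucocorticoid lists.

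**Figure D3:**
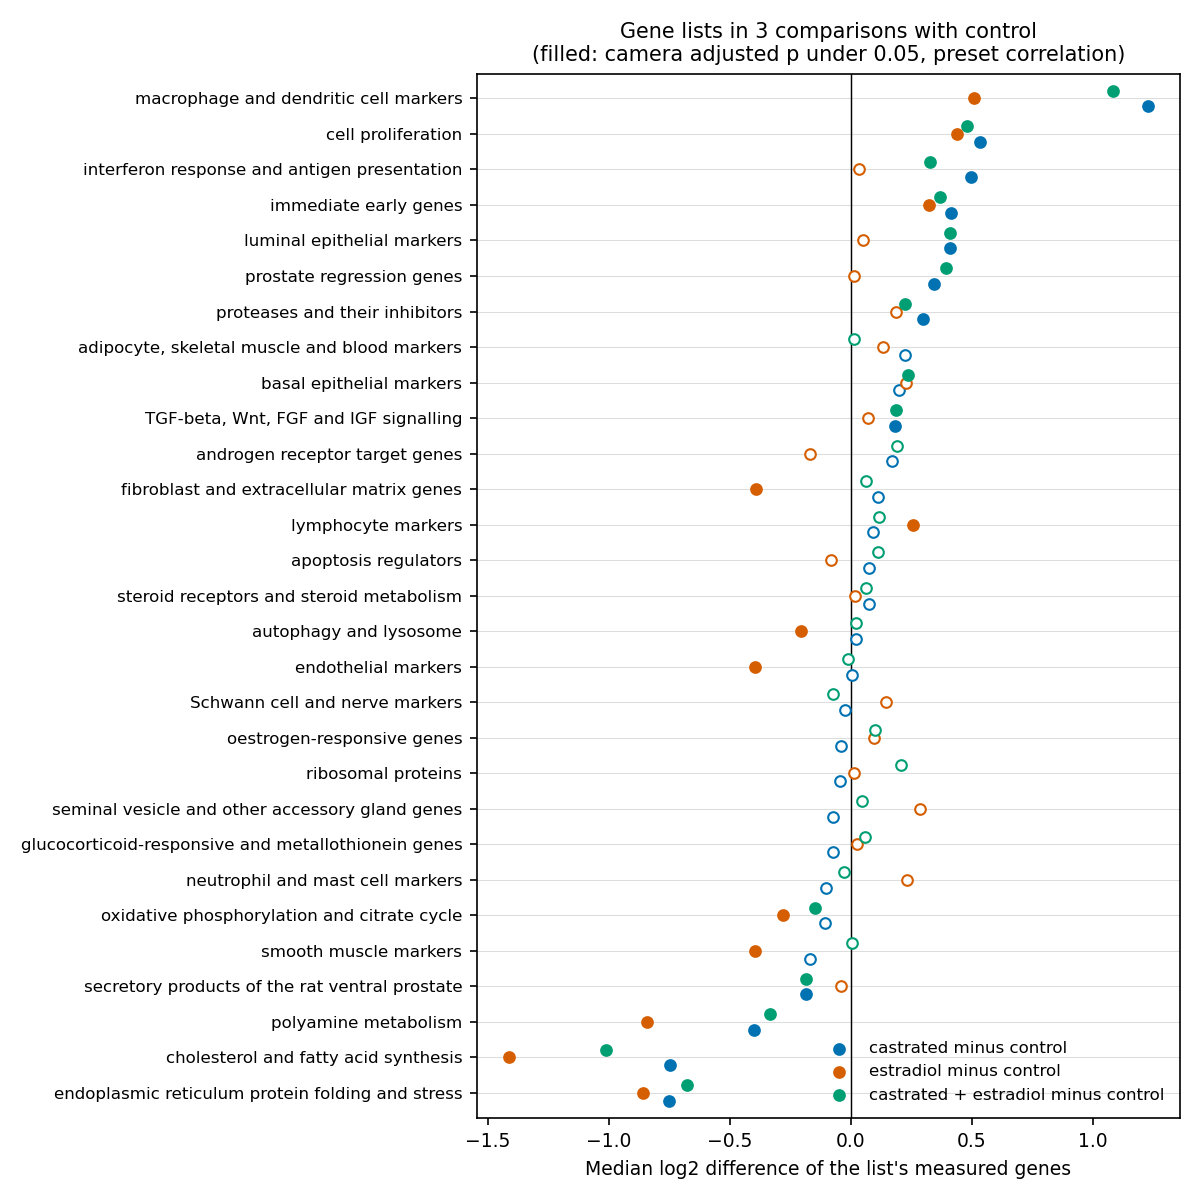
Median log2 difference from control of the measured genes of each of the 29 lists (horizontal axis) in castrated, estradiol-treated and combined-treated animals; filled points passed camera's adjusted threshold of 0.05 with the preset correlation, and none passed with an estimated correlation. The macrophage and dendritic cell list has medians of 1.23, 0.51 and 1.08, and the cholesterol and fatty acid list of -0.75, -1.41 and -1.01.

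The same genes were called by several treatments, and no gene called by 2 treatments went in opposite directions. All 3 treatments raised 154 genes and lowered 236, that is 390 of the 1538 called in any. Castration and the combined treatment shared 535 genes in direction (272 rose, 263 fell), 85.3% of those called under the combined treatment, where independent lists would share 9.74 and 7.57. Castration and estradiol shared 463 (181 rose, 282 fell; 11.5 and 18.8 for independent lists), and estradiol and the combined treatment 443 (160 rose, 283 fell; 7.70 and 17.5). Simulated groups without any effect, set against shared simulated controls, shared at most 0 genes. A simulation without effects has few calls to share, so this count cannot show how far shared controls raise the overlap. Across genes, which are not independent replicates, the log2 differences correlated at r = 0.905 between castration and the combined treatment, 0.663 between estradiol and the combined treatment, and 0.587 between castration and estradiol. Simulated groups gave 0.532, 0.455 and 0.474 in that order. The covariances were 0.148, 0.129 and 0.120 against simulated values of 0.0154, 0.0136 and 0.0150. The share of genes with the same sign was 77.5%, 67.3% and 60.1%, against 69.2%, 65.0% and 67.3% in the simulations. For castration and estradiol this share was below the simulated one. The simulated values already include shared controls. Part of the excess of shared genes over independent lists may come from the shared controls.

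These overlaps moved with the arrays in the fit as the counts did. With only the compared arrays the shared counts were 1605 for castration and the combined treatment, 183 for castration and estradiol, 188 for estradiol and the combined treatment and 181 for all 3. Without control 2 they were 226, 192, 185 and 167, and without estradiol 1 they were 1200, 866, 838 and 754. All 3 treatments shared 210 genes without control 1, 186 without control 3, 256 without castrated 3, 226 and 230 without combined 1 or 3, and 631 without estradiol arrays 1 and 2.

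Combined-treated animals were compared with castrated animals to find what estradiol added once the testes were gone. The groups may also differ by the injection, as vehicle is not stated for animals that were only castrated. Of the named genes Gpx3 differed most, at 11.55 ± 0.34 against 9.40 ± 0.20, a log2 difference of 2.15. By limma no gene passed in the fit of all 12 arrays, with a smallest adjusted p of 0.376 and 153 genes at an unadjusted p under 0.05, fewer than the 725.3 that chance would give with the right spread. Gpx3 alone passed when only the 6 compared arrays were fitted (adjusted p = 0.0218, 697 genes at an unadjusted p under 0.05), without estradiol 1, and without estradiol arrays 1 and 2 (adjusted p = 0.0248, 911 genes), and 13 genes passed with array quality weights. The 95% interval of a difference had a median half-width of 0.420, and 15 genes differed by more than 1. The differences between genes had an SD of 0.178. Of the lists, ribosomal proteins were higher (median 0.17, camera adjusted p = 6.38e-07), and cholesterol and fatty acid synthesis (median -0.25, 8.55e-05), macrophage and dendritic cell markers (-0.25, 8.55e-05), interferon and antigen presentation (-0.17, 0.00181) and adipocyte, skeletal muscle and blood markers (-0.13, 0.0156) were lower. Each had adjusted p = 0.74 with an estimated correlation, and by limma none of their members passed adjusted over all genes, nor adjusted over the list alone except 1 interferon gene that was lower. All 5 calls ended with fry. The adipocyte, muscle and blood call also ended without estradiol arrays 1 and 2 (adjusted p = 0.0692), without dim genes, without combined 1 and with array weights, that of cholesterol without castrated 1, that of interferon without combined 2, and that of macrophages without castrated 3 or combined 2. Leaving out castrated 3 turned the direction of the interferon list, and leaving out castrated 2 that of the adipocyte, muscle and blood list.

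Combined-treated animals were also compared with intact animals given estradiol, which differ in the presence of the testes and in the surgery and anaesthesia of castration. No gene passed in limma's fit of all 12 arrays (smallest adjusted p 0.241, 2742 genes at an unadjusted p under 0.05), nor with only the 6 compared arrays (1146). In the fit without estradiol arrays 1 and 2, 2 genes passed, both lower in combined-treated animals: Msmb, beta-microseminoprotein (-4.83), and Semg1, semenogelin (-6.62), with 552 genes at an unadjusted p under 0.05. Both were named after their values were seen and stood high on estradiol array 3, at 8.47 and 9.46, and at most 4.18 and 3.43 on any other array. Without estradiol 3, 4153 genes passed, and with array quality weights 489. Those weights rest the estradiol group mostly on array 2, which has the narrow range of values. Camera called 15 lists, and 11 without estradiol arrays 1 and 2. Endothelial (median 0.37, adjusted p = 6.34e-05), fibroblast and matrix (0.47, 0.000129) and smooth muscle markers (0.46, 0.00141) were higher under the combined treatment and stayed called without those arrays, with medians of 0.32, 0.37 and 0.34. Each of the 3 lists had 6 members higher adjusted over the list alone and adjusted p = 0.499 with an estimated correlation. The smooth muscle call ended under quantile normalization and without dim genes, and fry called none of the 29 lists. Of the other 12 lists only luminal markers kept their call without those arrays, and macrophage markers passed in the opposite direction. The calls that ended were those of the apoptosis, regression, protease, cholesterol, oxidative phosphorylation, autophagy, growth factor and interferon lists, all higher, and of the lymphocyte and Schwann cell lists, both lower.

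Intact animals given estradiol were compared with castrated animals to set the effects of both procedures against each other. No gene passed in limma's fit of all 12 arrays (smallest adjusted p 0.0792, 3956 genes at an unadjusted p under 0.05) or with only the 6 compared arrays (1421). When estradiol arrays 1 and 2 were left out, 6 genes passed, all higher under estradiol: Aox3 (2.50), Gpx3 (2.57), the haem-binding Hpx (1.59), Msmb (4.58), Pdlim3 (2.22) and Semg1 (6.55), all but Gpx3 named after their values were seen, with 701 genes at an unadjusted p under 0.05. The count was 5417 without estradiol 3, 1 without estradiol 2 and 1627 with array quality weights, and 5 probe sets passed when all were tested. Fibroblast and matrix markers were lower under estradiol than after castration (median -0.66, camera adjusted p = 0.000778, 8 lower adjusted over the list alone), as were endothelial (-0.32, 0.000197, 6 lower) and cholesterol synthesis genes (-0.38, 0.000161). These calls held without estradiol arrays 1 and 2, and had adjusted p = 0.483, 0.435 and 0.483 with an estimated correlation. The fibroblast call ended without dim genes, and those of fibroblast and cholesterol genes with fry. Macrophage and dendritic cell markers were lower under estradiol (-0.70, 3.16e-05, 6 lower adjusted over the list alone; adjusted p = 0.483 with an estimated correlation), which ended without those arrays (median -0.13, adjusted p = 0.358) and with fry. Apoptosis regulators were lower as well (-0.30, 0.00334, 7 lower adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), a call that ended without those arrays and without dim genes and held with fry. Camera called 14 lists in all, and those of androgen targets, regression, proteases, oxidative phosphorylation, autophagy and interferon also ended without those arrays. The 1 list called higher under estradiol was that of seminal vesicle and other accessory gland genes. Of its 12 genes, 4 were higher at an unadjusted limma p under 0.05 and 0 lower. Of 20 alternatives, its call ended in 2, quantile normalization and an estimated correlation. Quantile normalization is the alternative that evens out the narrow range of estradiol arrays 1 and 2. Without those arrays the call rests on estradiol array 3 alone. Centring array medians moved the median of all genes in this comparison from -0.01 to -0.14.

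The interaction asks whether estradiol changed genes by a different amount in castrated than in intact animals. It differed for 159 genes, with 113 positive and 46 negative differences, and without estradiol arrays 1 and 2 for 393, with 155 positive and 238 negative ones. The largest positive values were those of Cpa6 (3.64 ± 0.38), Oas1k (3.42 ± 0.41), Neto2 (3.28 ± 0.39), Elovl6 (3.27 ± 0.51), Wfdc3 (3.26 ± 0.52) and Derl3, of endoplasmic reticulum degradation (3.08 ± 0.51). The largest negative values were those of Mep1b (-4.23 ± 0.35), Lrrc34 (-3.13 ± 0.56), the sulfatase Sulf1 (-2.91 ± 0.60), Atp6v1c2 (-2.88 ± 0.32), Gpnmb (-2.77 ± 0.49) and Abcc3 (-2.56 ± 0.33). Adjusted p-values ran from 0.000226 for Mep1b to 0.0358 for Sulf1. Clu (-1.66), Gadd45b (-1.73), Fosl2 (-1.34), Jun (-1.22), Ifit1 (-2.44) and Aif1 (-1.48) had negative values that passed, and Scd (2.13), Fkbp5 (1.43), Acsl3 (1.47), Ccnd1 (1.45) and Fhl2 (1.61) positive ones, while Pbsn did not pass (5.51 ± 1.33, adjusted p = 0.0741). All 159 interaction values were opposite in sign to the differences of both castration and estradiol from control. A gene moved alike by all 3 treatments has such a value even where estradiol changed little in castrated animals. Of the 159, 154 passed after castration, 156 under estradiol, and 139 in the same direction under all 3 treatments. Cpa6 differed from control by -3.82, -3.78 and -3.97 after castration, estradiol and both.

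Camera called 11 lists. Endoplasmic reticulum folding had 6 of 35 positive values that passed (26 adjusted over the list alone) and a median of 0.81 (camera adjusted p = 1.02e-19, adjusted p = 0.094 with an estimated correlation), with Sdf2l1 (2.17) and Ssr4 (1.41). Cholesterol and fatty acid synthesis had 7 of 24 (15 adjusted over the list alone), with Tm7sf2 (1.84) and Lss (1.64), and a median of 1.15 (camera adjusted p = 2.68e-13, adjusted p = 0.341 with an estimated correlation). Polyamine metabolism had 3 of 15 (9 adjusted over the list alone), with Amd1 (1.15) and Srm (1.93), and a median of 0.82 (camera adjusted p = 5.65e-06, adjusted p = 0.094 with an estimated correlation). Macrophage and dendritic cell markers had a median of -0.71 with 1 of 26 passing, and proliferation genes of -0.60 with 1 positive value passing and 1 positive and 8 negative adjusted over the list alone (camera adjusted p = 3.01e-06 and 7.15e-06, adjusted p = 0.535 with an estimated correlation for each). These 2 list calls ended with fry, and that of proliferation with array weights. Without estradiol arrays 1 and 2, 136 of the 159 kept sign and call, the calls of the oxidative phosphorylation, autophagy and lymphocyte lists ended, and the regression, interferon and luminal lists passed as lower. The count was 88, 63 and 69 without control 1, 2 or 3, 99, 99 and 84 without castrated 1, 2 or 3, 389 and 1684 without estradiol 1 or 3, 65, 65 and 93 without combined 1, 2 or 3, and 1051 with array quality weights. Under quantile normalization the split was 97 positive and 71 negative. A moderated F test over the 4 groups called 793 genes, and 1743 without estradiol arrays 1 and 2.

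Over the 1159 genes changed by estradiol in intact animals, the difference that estradiol made in castrated animals had a slope of 0.00903 on the difference in intact animals (95% bootstrap interval over genes -0.00664 to 0.0246). These 2 differences share no array. Over the 803 genes changed by castration, the combined treatment's difference from control had a slope of 0.909 on that of castration (0.890 to 0.927) with shared controls and of 0.889 with no control array shared (0.871 to 0.907), and the difference that castration made among animals given estradiol a slope of 0.130 on that in intact animals (0.109 to 0.151). Estradiol's difference from control had a slope of 0.778 on that of castration over the same 803 genes (0.752 to 0.804) with shared controls and of 0.760 without (0.736 to 0.787). Castration's genes had been chosen on all 3 controls. Without estradiol arrays 1 and 2, the slope of 0.00903 became -0.0176 (-0.0363 to 0.00175) over the 733 genes called then, and that of 0.130 became 0.0662 (0.0404 to 0.0973) over 2408. The intervals treat genes as independent, which they are not.

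**Figure D4:**
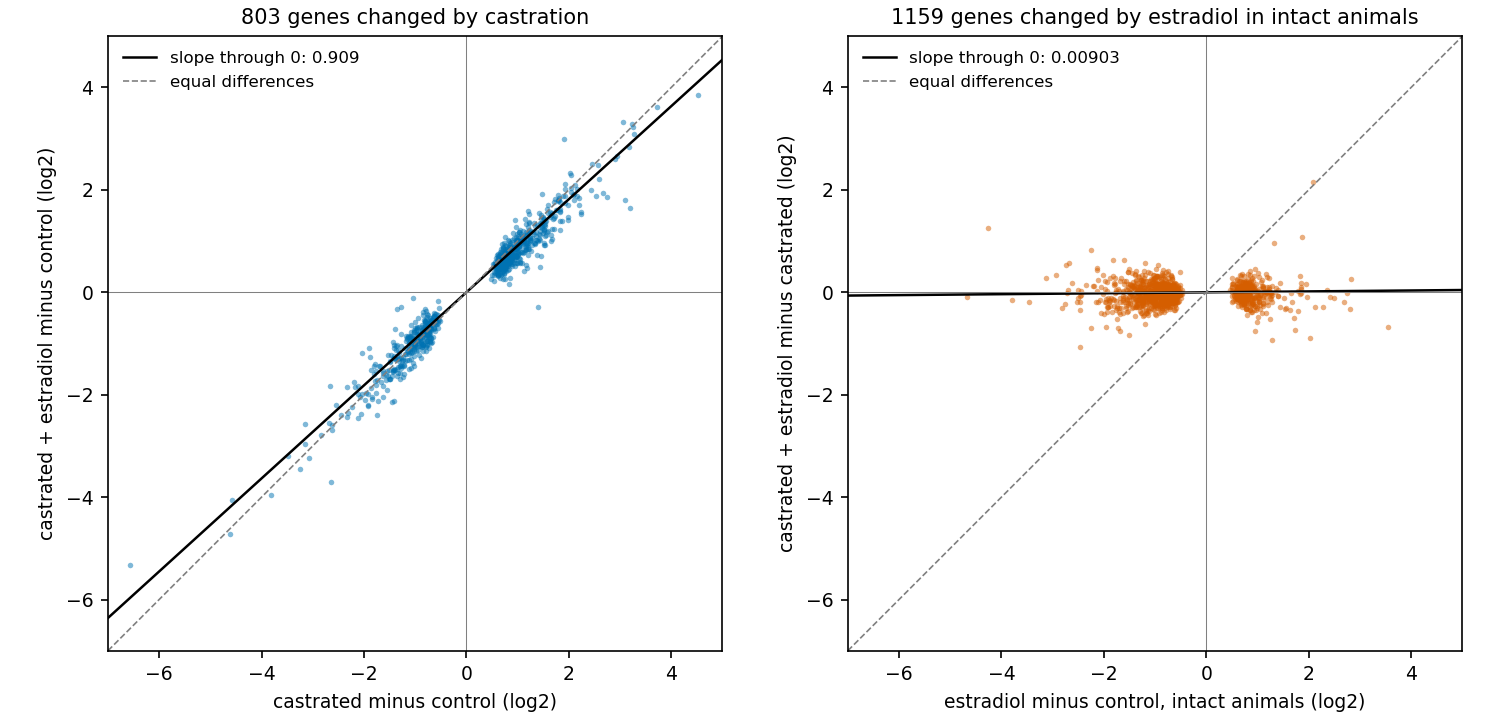
Log2 differences of single genes (points): left, combined-treated minus control against castrated minus control for the 803 genes changed by castration; right, combined-treated minus castrated against estradiol-treated minus control for the 1159 genes changed by estradiol in intact animals. The solid lines have slopes of 0.909 and 0.00903, and the dashed lines mark equal differences.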

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

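The tests of a narrower range of values, of whether estradiol arrays 1 and 2 alone made the interaction, and of a lower share of secretory cells were chosen after the results were seen, as was the split of the test of a stronger response into genes that rose and fell.

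Estradiol's effect differed between castrated and intact animals for 159 genes by the interaction test, which is why they are listed for a closer look. All 159 values were opposite in sign to the differences of castration and of estradiol from control. Of these genes, 139 passed in the same direction under all 3 treatments, so the values largely reflect a shift common to the treated groups. The largest positive values were those of Cpa6 (3.64), Oas1k (3.42), Neto2 (3.28), Elovl6 (3.27), Wfdc3 (3.26) and Derl3 (3.08), and the largest negative ones those of Mep1b (-4.23), Lrrc34 (-3.13), Sulf1 (-2.91), Atp6v1c2 (-2.88), Gpnmb (-2.77) and Abcc3 (-2.56). Of 100 splits of the 12 arrays into such groups, 2 gave as many genes, the real one included. These splits also undo the differences of every treated group from control, so they do not test the interaction by itself. The highest other split gave 290 genes, which points to a structure of the samples.

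Probe sets without a gene symbol, which the comparisons by gene did not use, also changed. Of 13581 such probe sets, 132 changed after castration (63 rose, 69 fell), 168 under estradiol (42 rose, 126 fell) and 88 under the combined treatment (27 rose, 61 fell). For estradiol against castrated 6 passed (5 higher, 1 lower) and for the interaction 15 (12 positive, 3 negative). What they measure was not analysed here.

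Splits of the arrays were counted for the other results as well. For each comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split was 1 of 10 with as many genes after castration (803, highest other 0), under estradiol (1159, highest other 1) and under the combined treatment (627, highest other 0). For combined against castrated, combined against estradiol and estradiol against castrated, all 10 splits gave at least the real count of 0 (highest other 0, 0 and 673). The 673 came from the split that put castrated 2 with estradiol 1 and 2, and they point to a structure of the samples. In the F test, only the real split of 100 gave as many as the real 793 genes (highest other 500). The real split is 1 of the 100, so no smaller share was possible and chance is not excluded.

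Estradiol arrays 1 and 2 stood apart from the other 10. Over 2930 genes without a difference between groups (unadjusted F test p above 0.5), their slopes on the mean of the control, castrated and combined arrays were 0.947 and 0.922, below the 0.971 to 1.02 of those 9 arrays and the 1.04 of estradiol array 3, so a compressed range of values is a candidate explanation. A stronger response in these animals would put the genes changed by the combined treatment further from control than on estradiol array 3. The median deviation in that direction was -0.0304 (error 0.0231) and -0.0472 (error 0.0160), but 1 median decides little, since genes that rose were lower by 0.30 and 0.25 (less response) and genes that fell lower by 0.26 and 0.18 (more), so it stays open. Cells of another tissue cannot be told apart either: the highest of 18 medians of marker lists, after removing the trend with level, was 0.487 for smooth muscle on array 1, with an error of 0.173 that spans the bound of 0.5. That bound was set for higher medians only. Macrophage and dendritic cell markers had the lowest medians, -0.698 (error 0.158) on array 1 and -0.659 (error 0.113) on array 2. These markers were thus lower on both arrays than on estradiol array 3.

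Estradiol changed fewer genes in castrated than in intact animals. The tables argue against arrays 1 and 2 as the sole source, since 136 of the 159 genes kept sign and call without them, though a lone estradiol array then remains. They also argue against an equal effect with and without testes, as the slope between the effects was 0.00903 (interval -0.00664 to 0.0246). Castration and estradiol bringing the same genes to the same level may account for the pattern: with no control array shared, estradiol's effect had a slope of 0.998 (0.960 to 1.04) on that of castration over the 1159 genes chosen for estradiol's effect and of 0.760 over the 803 chosen for castration, so it rests on the choice of genes. Whether estradiol acted by lowering testicular androgen was not tested, as no hormone level was used here.

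Secretory products were lower as a set after castration by camera at the preset correlation, though 2 of 20 genes fell and 1 rose, and the call ended with an estimated correlation and under quantile normalization. A lower share of secretory epithelial cells would lower luminal markers and raise those of every other cell type alike. The luminal list instead had a median of 0.41 (0.412, error 0.149), and the medians of the smooth muscle, fibroblast, endothelial and macrophage lists were -0.17, 0.11, 0.01 and 1.23 (error 0.12 for the last), which argues against it as the whole source. An increase of macrophages themselves stays open. Lower transcription in the luminal cells is the biological alternative, and it was not tested.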

How the results depend on the processing

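The fits without estradiol arrays 1 and 2 and those with array quality weights were chosen after seeing the data. Of 251 results of named genes that passed, centring array medians kept 231, quantile normalization 223, averaging probe sets 249, and a trend with a robust prior 247. Leaving out dim genes kept all 236 that stayed in, fitting only the compared groups 166 of 218, array weights 237, and leaving out estradiol arrays 1 and 2 kept 211. Leaving out control 1, 2 or 3 kept 175, 155 and 160 of the 251. No named gene that passed changed sign in any of these. Of 83 list results that passed, centring kept 81, quantile normalization 50, leaving out dim genes 52, fry 31, array weights 74, the fit without estradiol arrays 1 and 2 kept 55, and an estimated correlation 0.

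Where only the compared groups were fitted, the counts were 1872 for castration, 197 for estradiol (188 at least 2-fold), 2871 for the combined treatment and 1 for combined against castrated (1 at least 2-fold), and the overlaps were 183 for castration and estradiol, 1605 for castration and the combined treatment, 188 for estradiol and the combined treatment and 181 for all 3. The fit then has fewer arrays and its own estimate of spread.

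Without estradiol arrays 1 and 2 the counts were 2408 for castration, 733 for estradiol, 2105 for the combined treatment, 1 for combined against castrated (1 at least 2-fold), 2 for combined against estradiol (2 at least 2-fold), 6 for estradiol against castrated (6 at least 2-fold), 393 for the interaction (298 at least 2-fold) and 1743 in the F test. The overlaps were 1662 for castration and the combined treatment and 631 for all 3. The lone estradiol array was assumed to vary like the other groups.

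With array weights the counts were 3788 for castration, 2307 for estradiol, 4134 for the combined treatment, 13 for combined against castrated (4 at least 2-fold), 489 for combined against estradiol (179 at least 2-fold), 1627 for estradiol against castrated (356 at least 2-fold), 1051 for the interaction (521 at least 2-fold) and 5306 in the F test, with overlaps of 1021, 3069, 1193 and 989 in the order given above. Testing all probe sets gave 5 for estradiol against castrated (5 at least 2-fold). At an adjusted p under 0.01 the overlaps were 180, 222, 183 and 161, and at 2-fold 212, 270, 219 and 186, as stricter thresholds leave fewer genes. The cause of the other shifts was not tested.

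Leaving out each array in turn gave 361 to 1783 for castration, 390 to 5329 for estradiol (281 to 1237 at least 2-fold), 265 to 1484 for the combined treatment, 0 to 1 for combined against castrated (0 to 1 at least 2-fold), 0 to 4153 for combined against estradiol (0 to 732), 0 to 5417 for estradiol against castrated (0 to 977), 63 to 1684 for the interaction (63 to 881) and 231 to 4952 in the F test. The overlaps ranged from 192 to 866 for castration and estradiol, 226 to 1200 for castration and the combined treatment, 185 to 838 for estradiol and the combined treatment and 167 to 754 for all 3.

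Some list shifts changed direction, given as the negative log10 of camera's p, signed by direction. Without estradiol arrays 1 and 2 these were, for combined against estradiol, endoplasmic reticulum folding (-4.13 from 0.729), oxidative phosphorylation (-1.28 from 2.49), autophagy (-0.438 from 2.91), interferon (-0.192 from 2.17), macrophage (-1.81 from 3.14), Schwann cell (0.160 from -1.61) and ribosomal proteins (-3.05 from 0.852). For estradiol against castrated they were endoplasmic reticulum folding (6.02 from -0.165, and 2.34 under quantile normalization), proliferation (2.96 from -0.185), oxidative phosphorylation (0.966 from -2.37, and 0.0293 under quantile normalization), autophagy (0.130 from -2.71) and adipocyte, muscle and blood (-2.18 from 0.110), and for the interaction autophagy (-0.0415 from 2.55). When 1 array was left out, combined against castrated ranged from -10.6 to 1.17 for interferon, -4.30 to 2.51 for fibroblast and matrix and -5.29 to 0.910 for adipocyte, muscle and blood. The cause was not tested.

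Replicate numbers were not taken to pair the samples, since the labels state no pairing and not every pair correlated. Of 18 pairs of arrays with the same number, 7 had a correlation above 0.1 (-0.156 to 0.284, median 0.0723, against -0.025 for other numbers), and 8 of 12 arrays were closest to their own number. All 3 pairs of castrated with estradiol arrays were above 0.1 (0.144, 0.284 and 0.197), so pairing is not excluded there. With the number as a block, the counts were 825 for castration, 1255 for estradiol, 651 for the combined treatment, 0 for each comparison among treated groups, 150 for the interaction and 813 in the F test. The block kept 245 of the 251 gene results and all 83 list results. The narrow range of values on estradiol arrays 1 and 2 limits what small differences can be seen.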

Other observations

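The comparison of all arrays of animals given estradiol with all others was chosen after Gpx3 had been seen. Tests of single genes here are all exploratory.

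Gpx3, the glutathione peroxidase secreted into body fluids, followed estradiol rather than loss of the testes. It stood at 11.35 ± 0.59 on the 6 arrays of animals given estradiol and at 9.24 ± 0.38 on the other 6 (mean ± SD), with a gap of 0.76 between the nearest arrays. Its difference from control was 0.32 after castration, 2.08 under estradiol and 2.47 under the combined treatment. Pdlim3, a protein of muscle and cytoskeleton, was also higher on those 6 arrays (7.26 ± 0.57 against 6.12 ± 0.23), as was the metallothionein Mt2A (10.91 ± 0.35 against 10.20 ± 0.26). Lower on them were Hectd2 (-1.17), Cdo1, which breaks down cysteine (-1.07), Stx19 (-0.86), Fbxo33 (-0.77), Tmtc4 (-0.63) and Pigr, the receptor that carries antibodies into secretions (-0.42). Not all of these followed estradiol alone. After castration alone they differed from control by -0.58, 0.07, -0.56, -0.80, -0.14 and 0.33, in that order. Combined minus castrated was -0.83, -1.02, -0.29, -0.35, -0.38 and -0.52. For Pdlim3 and Mt2A castration gave -0.21 and 0.33, and combined minus castrated 0.96 and 0.45.

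In all, 174 genes separated the 6 arrays from the other 6 without overlap, 49 higher and 125 lower, where chance gives 31.4 (0.216% of genes). Of all splits of the 12 arrays 6 against 6, 5 gave as many genes, the real one included. This rank cannot settle the source of the count, because the split was chosen after a gene that separates it had been seen. The estradiol arrays with the narrow range of values also lie on the same side of it. Castrated against not castrated separated 174 higher and 50 lower genes, more than the split by estradiol. The highest other split gave 496, which points to a structure of the samples, and the median of the others was 17.

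Estradiol array 3 had Semg1 and Msmb far above every other array. Semg1 was 9.46 on it and 2.62 to 3.43 on the others, Msmb 8.47 and 3.54 to 4.18. Pbsn was 9.71, where the highest of the other 5 arrays of animals given estradiol was 7.45. Defb50 was 6.72, where the highest other was 6.05. Svs4 (5.91) was above those 5 arrays (at most 5.52) and within the range of all others, and Tgm4 (4.62) and Svs5 (3.54) lay within it and Svs6 (2.43) below it. Slopes on castration's difference from control, with shared controls, were taken over 535 genes called after castration and under the combined treatment. Estradiol array 3 had a slope of 0.845 (0.788 to 0.891), or 0.870 without Pbsn. Estradiol arrays 1 and 2 had 0.795 and 0.827, and the combined arrays 0.982, 0.874 and 1.02. The combined arrays took part in choosing these genes, which favours higher slopes on them.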
